A study of Mus musculus with 15 samples.

How the data were processed

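RNA was measured in 15 libraries of FACS-purified mouse cardiomyocytes, 5 for each of 3 AAV vectors (GFP, ATF4 with GFP, DDIT3 with GFP). Per the labels, the vectors were injected on postnatal day 1 into mice carrying Cas9 and GFP at the Rosa locus, hearts were digested by Langendorff perfusion at 4 weeks of age, and polyA RNA was turned into libraries with the SMART-Seq v4 and Nextera XT kits. The label of GFP replicate 5 names SMART-Seq3 where those of the other 14 libraries name SMART-Seq2. Per the submitters' processing notes, the tools were STAR, featureCounts, DESeq2 and DESeq and the genome build was mm10, with versions not given in the sources used here.

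The deposited table of read counts per gene, which the authors made from their reads, holds whole-number counts of 23337 genes in 15 libraries and gave every result except those credited to the authors' tables. Its gene length column (other unit), as deposited, was used in the check of length bias. The authors also deposited 2 tables of their own comparisons against GFP. Per the file headers these hold a mean signal (the mean normalised count), a log2 fold change with its standard error, a test score (the Wald statistic) and p-values, raw and adjusted. They were used only where the text names the authors' deposited table. The authors' mean signal matched the mean of the counts divided by median-of-ratios factors over the 10 libraries compared in 100% of genes with a mean above 1, within 0.1%, and over all 15 libraries in 0.9% and 0.7%. Their log2 fold changes correlated with the edgeR values across 11798 genes at 1.00 for ATF4 and 0.997 for DDIT3. Of the gene symbols, 25 had been turned into dates, and the 13 genes of the mitochondrial genome looked for were not analysed here. The kit does not mark strand, so that overlapping antisense genes and near-identical copies, such as Hba-a1 and Hba-a2 and ribosomal protein genes with pseudogenes, are uncertain.

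Groups and replicate numbers came from the sample titles. Nothing in the labels says which libraries came from separate animals, so that p-values measure the spread between these samples. Libraries of 1 group were compared by a chi-square test over genes with at least 20 counts in the pair: chi-square per degree of freedom was 8.60 to 50.4, so none was a copy of another. Counts were tested with edgeR's quasi-likelihood test (robust glmQLFit, TMM factors, filterByExpr) in 1 fit of 15 libraries with the group as the only term (12 residual degrees of freedom, common biological coefficient of variation 19.6%), with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter left 11814 genes and removed 11523. Fold changes are ATF4 or DDIT3 relative to GFP, or ATF4 relative to DDIT3, on the log2 scale with their standard errors. CPM use TMM factors. The groups' own errors are SD over 5 libraries. Totals of 6217744 to 8317249 counts per library set the depth, and the intervals of ratios (95%, exact binomial) and the floor of 3 counts over a group cover counting error only.

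Gene lists (32), the rule for naming genes and the alternatives, apart from 3 named below, were fixed before the data were examined. Set tests used 29 of them, leaving out the mitochondrial genome, the sex-linked genes and the erythroid markers, of which 2 were tested. Sets were tested with camera at a preset correlation of 0.01, two-sided, adjusted over the 29 lists, then with an estimated correlation and with fry. Fry at an adjusted p below 0.05 called 23 lists in ATF4 against GFP, 1 in DDIT3 against GFP (cardiac ion channels, adjusted p = 0.0450) and 23 in ATF4 against DDIT3. Lists overlap: 45 of their 695 genes stand in more than 1, and the ATF4 list shares 9 genes with the transporters, 9 with the one-carbon enzymes, 6 with the DDIT3 (CHOP) list, 2 with the p53 targets and 1 with the NRF2 list. The fetal and stress-induced cardiac list shares 4 genes with the atrial, 2 with the pericyte, 1 with the fibroblast and 1 with the p53 list. Marker scores are mean log2 CPM (prior count 2) over the tested genes of a list, compared by exact permutation tests over 7 lists and 3 comparisons (21 tests, smallest possible p 0.00794). The text names Atf4 and Ddit3, the 10 largest rises and 10 largest falls of each comparison with GFP (6 each for ATF4 against DDIT3) among genes called, of at least 5 CPM in the higher group and with groups that do not overlap, up to 3 members with the lowest p of each list, 19 heart and stress genes whatever their test, and 4 genes called in opposite directions. Genes with provisional symbols were passed over for naming, and a few results are not reported here.

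Same-numbered libraries were checked for pairing by the correlation of their deviations from the group means across genes. For DDIT3 and GFP all 5 correlations exceeded 0.1 (0.205 to 0.511), as they did for ATF4 and DDIT3 (0.135 to 0.497), so that the numbers appear to pair these samples, although no label says what a number marks. For ATF4 and GFP 4 of 5 did. The main fit and the exact permutation tests between groups did not use this pairing. Fits with the number as a block are given as an alternative. An exact test on 5 pairs could not give a p below 0.0625.

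The steps were tested on simulated data drawn from the means, dispersions and library sizes of the counts with 200 genes changed. For ATF4 against GFP, with 11505 genes tested, edgeR recovered 28.4% of 1.5-fold, 71.6% of 2-fold and 98.5% of 4-fold changes with 2.9% false calls. For DDIT3 against GFP, with 11497 genes, it recovered 31.3%, 73.1% and 93.9% with 5.7% false calls. Alternatives were DESeq2, limma-voom, DESeq2 size factors and upper-quartile factors in edgeR, no filter, a filter of 5 CPM in 5 libraries, the 2 compared groups alone, the replicate number as a block, sex as a covariate, a 2-fold minimum and leaving out each library. Chosen after seeing the data were the block together with sex, the male libraries alone and a fit without the 3 libraries numbered 2. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Coordinates are those of a GENCODE annotation of mm10.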

Results

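Cardiomyocyte RNA was sequenced from the hearts of 4-week-old mice that had received an adeno-associated virus (AAV) vector on postnatal day 1. AAV is a viral vehicle that carries a gene into cells of a living animal. The vector encoded GFP alone (the control group), ATF4 together with GFP, or DDIT3 together with GFP, with 5 libraries in each of the 3 groups. ATF4 is a transcription factor of the integrated stress response that activates genes of amino acid synthesis and transport, and DDIT3, also called CHOP, is a transcription factor induced by endoplasmic reticulum (ER) stress. Total counts per library lay between 6680988 and 7963333 in GFP, 6217744 and 7514376 in ATF4, and 7268663 and 8317249 in DDIT3. Of 23337 genes in the table, 5744 had no count in any library and 11814 had enough counts to be tested. Myh6, the adult cardiac myosin heavy chain, was the most abundant transcript of every library and took 5.82 ± 1.02% of the counts in GFP, 5.10 ± 0.921% in ATF4 and 5.32 ± 0.369% in DDIT3 (SD, n = 5). Xist and 4 Y-linked transcripts marked 11 libraries as male and 4 as female, namely ATF4 replicate 2, DDIT3 replicate 2 and GFP replicates 4 and 5. A principal component analysis placed the ATF4 libraries apart from the others on the first component (54.4% of the variance), while ATF4 replicate 2 and DDIT3 replicate 2 had the highest scores on the second (40.6 and 35.2, with 11.4% of the variance).

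Both vector genes were raised in the group that carried them. Atf4 (chromosome 15, 80255184 to 80257541, mm10) stood at 400 ± 79.5 CPM (counts scaled to the size of the library) in the ATF4 group against 71.1 ± 12.2 CPM in GFP and 66.5 ± 22.9 CPM in DDIT3 (SD, n = 5). Its log2 fold change against GFP was 2.49 ± 0.21 (SE, edgeR adjusted p = 4.1e-08). Ddit3 stood at 844 ± 180 CPM in the DDIT3 group against 15.6 ± 1.28 CPM in GFP, a log2 fold change of 5.75 ± 0.20 (edgeR adjusted p = 2.3e-12). Ddit3 was also higher in the ATF4 group, at 29.5 ± 7.62 CPM (0.91 ± 0.17, edgeR adjusted p = 6.1e-04), while Atf4 in the DDIT3 group differed from GFP by a log2 value of -0.10 ± 0.20 (edgeR adjusted p = 0.946). Counts per gene do not separate transcripts of the vector from those of the animal's own gene.

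**Figure D1:**
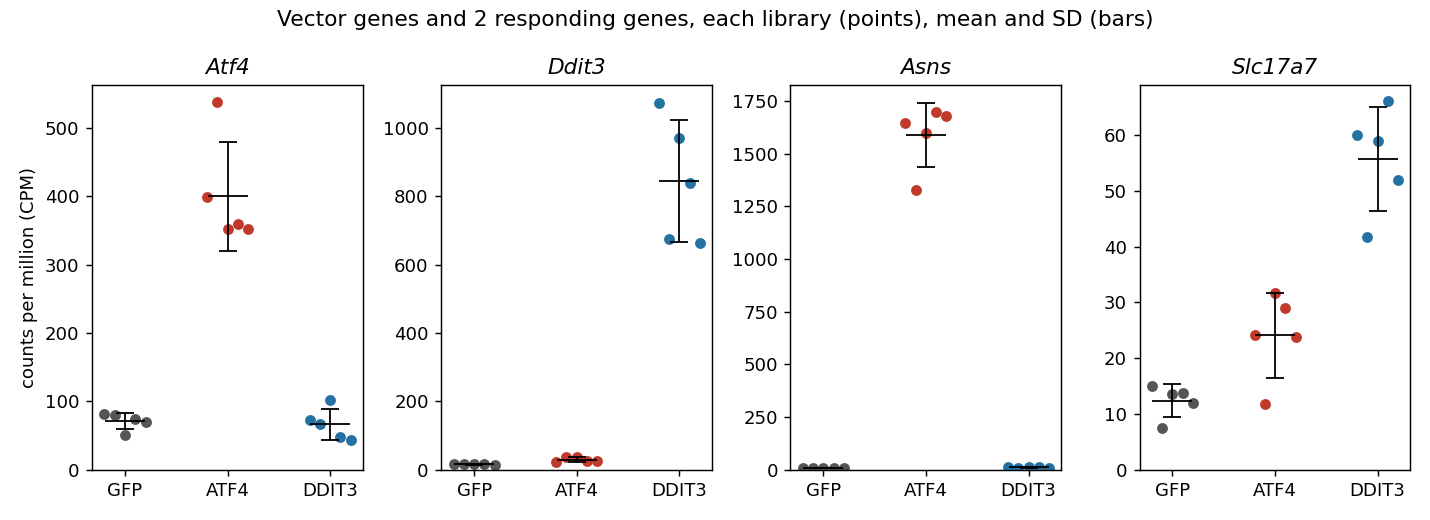
CPM (linear axes from 0) of Atf4, Ddit3, Asns and Slc17a7 in each of the 15 libraries (points), with the mean and SD of each group of 5 (bars). Asns averaged 7.63 CPM in GFP and 10.8 CPM in DDIT3 and 1589 CPM in ATF4, while Slc17a7 was highest in the DDIT3 group (55.8 CPM).

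The first comparison asked which transcripts changed when ATF4 was raised in cardiomyocytes. Fgf21, a hormone of the fasting and stress responses, rose from 2 counts in all GFP libraries together to 485.7 ± 120 CPM, a ratio of 8663 (95% counting interval 2398 to 71540). Slc7a3, a cationic amino acid transporter, Slc7a11, the cystine transporter, and Cntnap3 each had 1 count in GFP. They rose to 298 ± 27.4, 104 ± 24.4 and 66.0 ± 18.4 CPM, ratios of 10633 (1908 to 420034), 3732 (669 to 147446) and 2370 (425 to 93646). Phgdh, the first enzyme of serine synthesis, rose from 0.106 to 346 CPM (log2 fold change 11.39 ± 0.30, edgeR adjusted p = 4.7e-15) and P2rx3, an ATP-gated channel, from 0.2996 to 376 CPM (10.18 ± 0.35, adjusted p = 1.45e-13). Soat2, Adm2, Gjb2 and Mei4 had no count in GFP and were at least 535-fold, 380-fold, 377-fold and 191-fold higher, against a floor of 3 counts over the group. The deepest falls were smaller: Sbk2 -3.55 ± 0.44, Sema6c -2.79 ± 0.30, Clcn1 -2.73 ± 0.43, Dbh -2.67 ± 0.33, Slc9a2 -2.63 ± 0.36, Kcne1 -2.57 ± 0.24, Pdzrn4 -2.51 ± 0.30, Hnmt -2.25 ± 0.24, Lrrc15 -2.22 ± 0.36 and Cubn -2.16 ± 0.42 (log2 fold change ± SE, edgeR adjusted p of 0.00066 or less). Dbh makes noradrenaline, Kcne1 is a potassium channel subunit and Clcn1 is a chloride channel.

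Genes of amino acid supply rose together. Of 39 tested members of the ATF4 and amino acid response list, 34 rose, 0 fell and 5 did not pass the test, with a list median log2 fold change of 4.60 and the same 34 when adjusted over the list alone. Examples were Asns, asparagine synthetase (7.70 ± 0.18, 1589 against 7.63 CPM), Trib3, a pseudokinase (7.57 ± 0.23), Aldh18a1, the first enzyme of proline synthesis (5.19 ± 0.11), and Chac1, which degrades glutathione (4.73 ± 0.26). The 5 others were Ppp1r15a (0.52 ± 0.29, edgeR adjusted p = 0.177) and Ddit4, Atf3, Cebpb and Vldlr, these 4 named after their values were seen. Of 18 serine, glycine and one-carbon enzymes, 12 rose, among them Mthfd2 of the mitochondrial folate cycle (9.01 ± 0.26), and Mthfd2l and Gcsh fell (-0.88 ± 0.20 and -0.47 ± 0.15), these 2 named after their values were seen. Of 23 amino acid transporters 15 rose, with Slc7a5 at 7.32 ± 0.22, Slc1a4 at 6.24 ± 0.20 and Slc3a2 at 4.10 ± 0.21, and 2 fell (3 when adjusted over the list alone). Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 16 rose and 0 fell, with Cars at 3.57 ± 0.10, Gars at 3.52 ± 0.10 and Nars at 3.42 ± 0.10. All 4 lists ranked above other genes with a preset correlation and with an estimated one (camera, largest adjusted p with an estimated correlation 8.0e-05).

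The targets of DDIT3 and of neighbouring stress pathways also moved. Of 20 members of the DDIT3 (CHOP) and cell death list, 12 rose and 2 fell (camera adjusted p = 7.5e-06 with an estimated correlation), with Nupr1, a stress-induced chromatin protein, at 8.59 ± 0.29. Of these 20, 6 also stand in the ATF4 list and 2 in the synthetase list. Of these 8, 6 rose (median 4.01), and of the other 12, 6 rose and 2 fell (median 0.787). Of 32 genes of ER chaperones and ER-associated degradation, 14 rose and 0 fell (17 and 1 with the replicate number as a block), among them Ern1, an ER stress sensor (2.05 ± 0.17), Herpud1 (1.48 ± 0.13), Dnajb9 (1.35 ± 0.12) and Xbp1 (0.98 ± 0.14). Hspa5, the main ER chaperone, stood at a log2 fold change of -0.00 ± 0.14 (1227 against 1228 CPM, edgeR adjusted p = 0.996). The ER list was called by camera with the preset correlation and by fry, but not by camera with an estimated correlation (adjusted p = 0.239). Of 21 NRF2 and glutathione genes 14 rose (15 when adjusted over the list alone) and 2 fell, with Hmox1, heme oxygenase, at 4.17 ± 0.21 and Srxn1, sulfiredoxin, at 2.43 ± 0.16 (camera adjusted p = 0.0338 with an estimated correlation). Of 18 p53 targets 10 rose and 2 fell (camera adjusted p = 0.00992 with an estimated correlation), with Gdf15, a secreted stress cytokine, at 6.60 ± 0.27, Sesn2 at 4.25 ± 0.13 and Perp at -0.90 ± 0.11. Gdf15 and Sesn2 also stand in the ATF4 list.

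Some transcripts of the adult heart muscle fell. Of 30 adult sarcomere and Z-disc genes, 12 fell (13 when adjusted over the list alone), with Myl3, a myosin light chain, at -0.82 ± 0.14, Tpm1, tropomyosin, at -0.63 ± 0.12, Tnni3, cardiac troponin I, at -0.56 ± 0.11 and Myom1 at -0.56 ± 0.11, and 1 rose. The riser, named after its value was seen, was Flnc at 0.64 ± 0.20. Myh6 differed by -0.35 ± 0.14 (edgeR adjusted p = 0.055, 0.0204 without ATF4 replicate 2, 0.0152 without GFP replicate 2 and 0.00502 to 0.174 over 27 alternatives). Of 23 excitation-contraction coupling genes 14 fell (15 when adjusted over the list alone) and 2 rose, with Atp2a2, the calcium pump of the sarcoplasmic reticulum, at -0.79 ± 0.15, its inhibitor Pln at -0.75 ± 0.10 and the calcium release channel Ryr2 at -0.47 ± 0.14. Of 25 cardiac ion channel and gap junction genes 18 fell and 2 rose (3 when adjusted over the list alone), a list still called with an estimated correlation (camera adjusted p = 0.0338). The potassium channels Kcnj3 and Kcnd2 stood at -1.66 ± 0.18 and -1.65 ± 0.14. The calls of the sarcomere and coupling lists were lost with an estimated correlation (adjusted p = 0.0936 and adjusted p = 0.239). Of 23 fetal and stress-induced cardiac genes 9 rose and 1 fell (11 and 2 when adjusted over the list alone or with the block, adjusted p = 0.0936 with an estimated correlation). Examples were Uchl1, a ubiquitin hydrolase, at 4.40 ± 0.14, skeletal actin Acta1 at 2.45 ± 0.32, slow troponin Tnni1 at 2.39 ± 0.32 and the natriuretic peptide Nppa at 1.39 ± 0.37. The fetal myosin Myh7 differed by 1.86 ± 0.80 (edgeR adjusted p = 0.0929), and over 27 alternatives its adjusted p ran from 0.0392 without ATF4 replicate 4, which alone called it, to 0.978 among male libraries alone. It was 0.652 without ATF4 replicate 2, and the block gave 0.986 ± 0.551 (adjusted p = 0.185). Its level was 4006 CPM in ATF4 replicate 2 and 104 to 666 CPM in the other 4 ATF4 libraries. Nppb differed by 0.72 ± 0.29 (edgeR adjusted p = 0.0651, 0.0133 without GFP replicate 2, 0.0341 without DDIT3 replicate 4 and 0.00329 to 0.189 over 27 alternatives).

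Most members of the respiratory, tricarboxylic acid cycle and fatty acid lists fell. Of 35 tested genes of respiratory complex I, 29 fell and 0 rose (32 fell when adjusted over the list alone), and the median log2 fold change was -0.59. Ndufs1 stood at -0.82 ± 0.12, Ndufa10 at -0.77 ± 0.10 and Ndufv1 at -0.58 ± 0.08. Of 37 genes of complexes II to V, 30 fell and 1 rose (33 and 1 when adjusted over the list alone), with Uqcrfs1 at -0.82 ± 0.13, Sdha at -0.77 ± 0.10 and Uqcrc1 at -0.73 ± 0.11. Cox8a, named after its value was seen, rose by 0.52 ± 0.11. Of 20 genes of the tricarboxylic acid cycle and pyruvate dehydrogenase 17 fell, with Sucla2 at -0.82 ± 0.11, Idh3b at -0.77 ± 0.11 and Mdh2 at -0.61 ± 0.10. Of 32 genes of fatty acid uptake and oxidation 21 fell and 1 rose (22 and 1 when adjusted over the list alone, 23 and 2 with the replicate number as a block), with Acaa2 at -0.89 ± 0.11, Eci1 at -0.78 ± 0.13 and Acadm at -0.74 ± 0.09. Fabp4, named after its value was seen, rose by 0.94 ± 0.21. Cpt1b, the muscle carnitine palmitoyltransferase, differed by -0.29 ± 0.13 (edgeR adjusted p = 0.106, 0.0467 without ATF4 replicate 3 and up to 0.244 over 27 alternatives). These 4 lists were called by camera with the preset correlation and by fry (adjusted p of 0.00255 or less). Camera gave adjusted p = 0.402 for both respiratory lists and adjusted p = 0.259 for the other 2 with an estimated correlation. Of 20 regulators of these genes 8 fell and 1 rose (camera adjusted p = 0.0613, called without ATF4 replicate 2 or GFP replicate 4, 0.0299 and 0.0382, and 0.0293 to 0.239 over its alternatives by camera), with Rxrg at -1.14 ± 0.16, Esrrg at 0.65 ± 0.13 and the coactivator Ppargc1a at -0.02 ± 0.28 (edgeR adjusted p = 0.963). Of 22 glycolysis genes 4 rose and 7 fell (4 and 8 when adjusted over the list alone, camera adjusted p = 0.32), with the glucose transporter Slc2a1 at 1.67 ± 0.18, Pfkp at 1.14 ± 0.13 and muscle enolase Eno3 at -1.03 ± 0.16. Of 16 mitochondrial chaperones and proteases 3 rose and 3 fell (3 and 4 when adjusted over the list alone, 3 and 6 with the replicate number as a block, camera adjusted p = 0.925), with the protease Lonp1 at 1.27 ± 0.09, Yme1l1 at 0.99 ± 0.14 and Hspa9 at 0.83 ± 0.11.

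Among markers of other cell types, 12 of 14 endothelial genes rose (13 when adjusted over the list alone) and 0 fell, with Ly6c1 at 0.97 ± 0.21, Tie1 at 0.91 ± 0.20 and Eng at 0.85 ± 0.17 (camera adjusted p = 0.00349 with the preset correlation, adjusted p = 0.437 with an estimated correlation). The mean log2 CPM of these 14 genes was 6.30 ± 0.269 in ATF4 and 5.49 ± 0.454 in GFP (SD, n = 5, two-sided exact permutation p = 0.00794, Benjamini-Hochberg adjusted 0.0417 over 21 marker tests). Of 11 pericyte and smooth muscle markers 6 rose (7 when adjusted over the list alone, camera adjusted p = 0.107, and 0.0459 without GFP replicate 2), with Cspg4 at 0.97 ± 0.16 and Pdgfrb at 0.92 ± 0.25. Of 13 fibroblast markers Postn rose (1.09 ± 0.32) and Fbln1 fell (-1.88 ± 0.14, 2 fell with the block), and of 8 tested leukocyte markers 0 passed edgeR (0 also when adjusted over the list alone). Of 11 atrial markers Nppa rose, and Kcnj3 and Stard10 (-0.89 ± 0.15) fell (3 fell with the block), with a list median of -0.60 (camera adjusted p = 0.107). Their mean log2 CPM was 3.11 ± 0.427 in ATF4 and 3.77 ± 0.312 in GFP (SD, n = 5). This difference of -0.658 had a two-sided exact permutation p = 0.0238 (Benjamini-Hochberg adjusted 0.1). The atrial list shares 3 genes with the ion channel list. Of 22 cell cycle genes 4 rose and 1 fell (7 and 1 with the replicate number as a block, camera adjusted p = 0.131), with cyclin Ccnd2 at 3.05 ± 0.14, Mcm6 at 1.20 ± 0.22 and Cenpf at -1.33 ± 0.27. Of 25 ubiquitin ligase and autophagy genes 7 rose and 3 fell (7 and 4 when adjusted over the list alone, 8 and 5 with the block, camera adjusted p = 0.63), with Sqstm1 at 0.92 ± 0.12, Ctsl at 0.76 ± 0.12 and Becn1 at 0.69 ± 0.09. Of 67 ribosomal protein genes 13 rose and 1 fell (9 and 1 when adjusted over the list alone, camera adjusted p = 0.118), with Rpl4 at 0.51 ± 0.10. Camera called this list without ATF4 replicate 2, GFP replicate 2 or GFP replicate 4 (adjusted p down to 0.0376). Of 22 immediate early genes Myc (3.65 ± 0.38) and Hspb1 (0.49 ± 0.14) rose and Jun fell (-1.16 ± 0.37). Of 19 interferon-stimulated genes 4 rose (1 when adjusted over the list alone, 9 with the block, camera adjusted p = 0.0685), with Ifi27l1 at 0.96 ± 0.17, Rsad2 at 0.90 ± 0.31 and Isg15 at 1.20 ± 0.42. Camera called this list without ATF4 replicate 2, GFP replicate 1 or GFP replicate 2 (adjusted p of 0.0299 or less). Besides the 17 lists of camera, fry called those of regulators, pericyte, atrial, cell cycle, autophagy and interferon genes (adjusted p of 0.0338 or less). The calls of Jun, Isg15 and Rsad2 were each lost without 5 or 6 single libraries, with edgeR adjusted p of up to 0.0632, 0.0867 and 0.11.

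In total 3801 of 11814 genes passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05 (32.2%), 1953 higher and 1848 lower in ATF4, and 1049 of them differed at least 2-fold (713 higher, 336 lower). The largest changes were rises, with 109 genes at least 16-fold higher and 0 at least 16-fold lower (edgeR estimates). In 2534 genes (21.4%) all libraries of one group lay above all of the other, where chance gives 0.794%. Of the 29 gene lists tested, camera called 17 (10 higher, 7 lower), and 8 with an estimated correlation. The authors' deposited table for this comparison gave 3956 genes at an adjusted p below 0.05 (1988 higher, 1968 lower), which included 3564 of the 3801, all in the same direction.

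**Figure D2:**
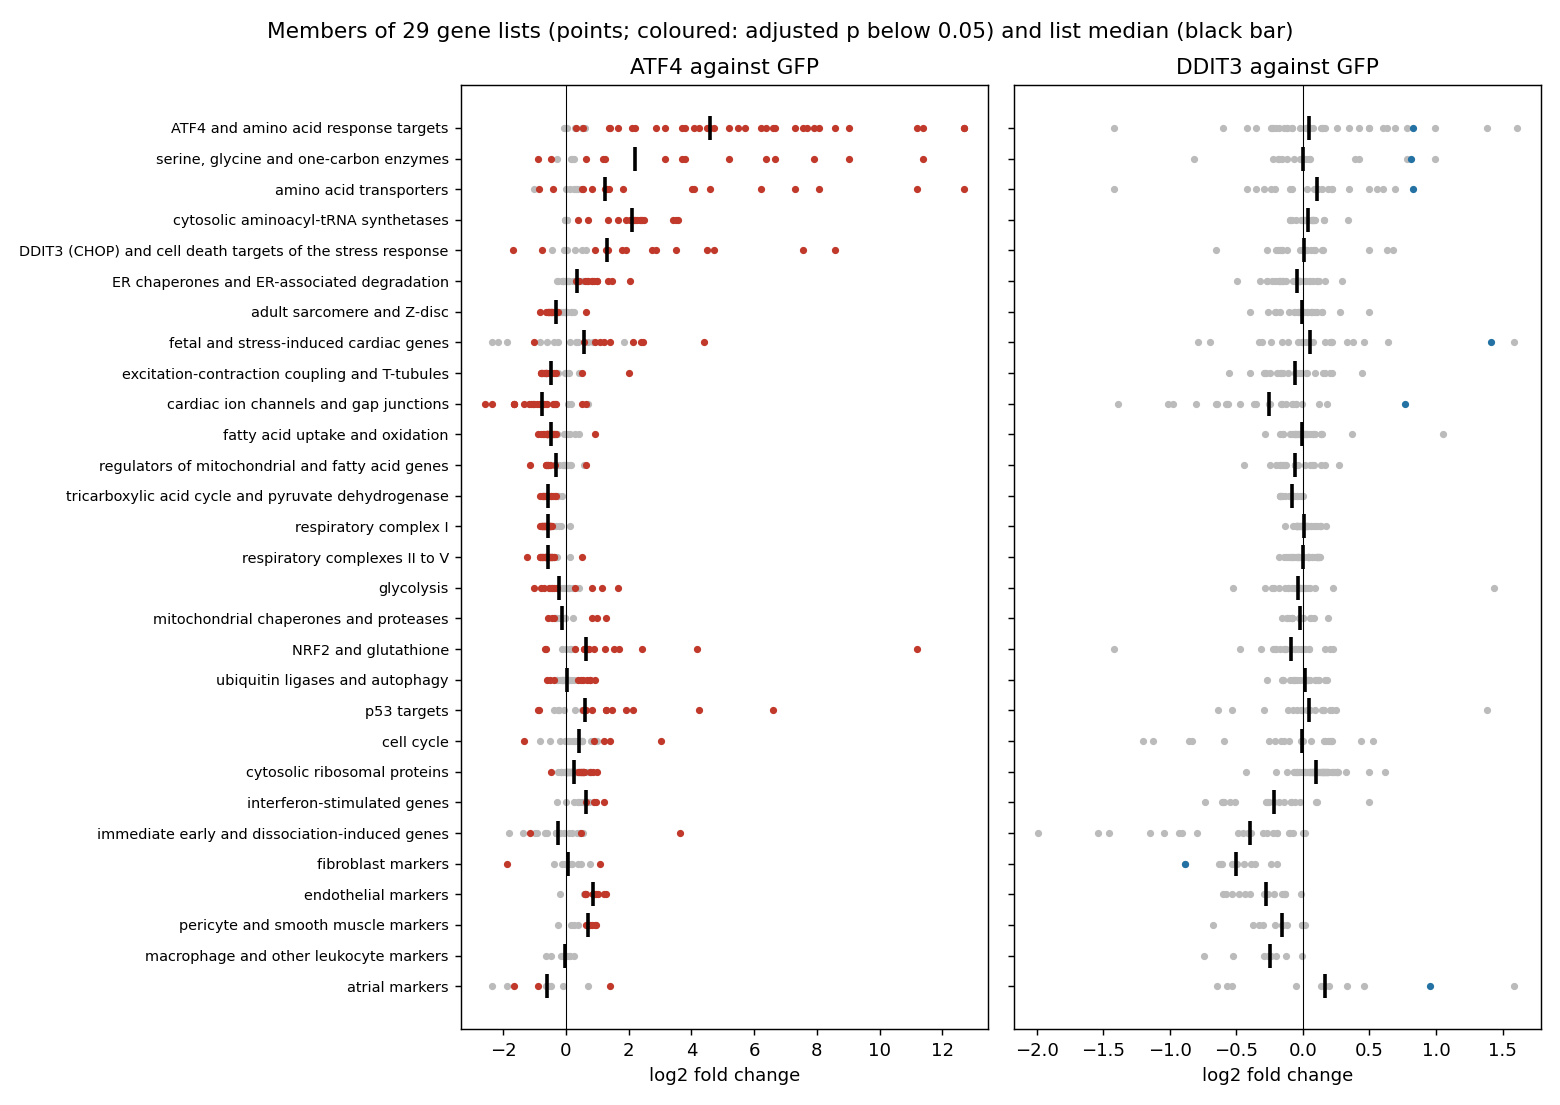
Log2 fold change against GFP of the members of 29 gene lists (points, coloured where the edgeR adjusted p is below 0.05) with the median of each list (black bar), for ATF4 (left) and DDIT3 (right, on a narrower axis). In ATF4 the amino acid response list has a median of 4.60 and complex I one of -0.59, while in DDIT3 their medians are 0.05 and 0.01.

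The second comparison asked the same of DDIT3. Besides Ddit3, the largest rises among genes of at least 5 CPM were Slc17a7, a vesicular glutamate transporter (2.17 ± 0.23, 55.8 ± 9.30 against 12.4 ± 2.90 CPM, edgeR adjusted p = 7.5e-05), Gnb3, a G protein subunit (2.07 ± 0.27, adjusted p = 8.4e-04), Adap1 (2.03 ± 0.30), Pcbd1 (1.86 ± 0.31) and Aplp1, a relative of the amyloid precursor protein (1.75 ± 0.28). Next came Ankrd35 (1.64 ± 0.29), Zfp385a (1.5 ± 0.25), Syt3, a synaptotagmin (1.41 ± 0.20) and Uchl1 (1.41 ± 0.13, 15.1 ± 1.55 against 5.63 ± 1.05 CPM). The deepest falls were Kcnv2, a potassium channel subunit (-2.51 ± 0.32, edgeR adjusted p = 6.2e-04), Mgst1, a membrane glutathione transferase (-1.59 ± 0.21), the Wnt inhibitor Wif1 (-1.56 ± 0.36) and Wisp1 (-1.40 ± 0.25). Smaller falls were those of Slit2, a secreted guidance protein (-1.39 ± 0.30), Prlr, the prolactin receptor (-1.39 ± 0.22), the carboxylesterase Ces1d (-1.33 ± 0.24), Gstm2 (-1.29 ± 0.16), Pknox2 (-1.11 ± 0.21) and Fam81a (-1.09 ± 0.24). The calls of Wif1, Slit2 and Fam81a, with edgeR adjusted p between 0.0341 and 0.0471, were lost without 13, 9 and 7 single libraries of the 15, with adjusted p of up to 0.1215, 0.0837 and 0.1187.

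None of the 20 tested members of the DDIT3 (CHOP) and cell death list passed edgeR (0 also when adjusted over the list alone, 1 with the replicate number as a block), and their median log2 fold change was 0.01, with Trib3 at 0.02 ± 0.28, Chac1 at -0.20 ± 0.27 and Ppp1r15a at -0.02 ± 0.29. Of the 39 ATF4 and amino acid response genes 1 rose, Slc3a2 (0.83 ± 0.19, edgeR adjusted p = 0.0432), 4 when adjusted over the list alone and 3 with the replicate number as a block, and Asns differed by 0.50 ± 0.15 (edgeR adjusted p = 0.188, 0.0487 with the replicate number as a block and up to 0.511 over 27 alternatives). Of the 23 amino acid transporters Slc3a2 rose (2 members when adjusted over the list alone or with the block), and of the 18 one-carbon enzymes Shmt1 rose (0.81 ± 0.19, 2 members when adjusted over the list alone or with the block). Of 25 cardiac ion channel and gap junction genes 1 rose and none fell over all genes, but 8 fell and 1 rose when adjusted over the list alone, with a list median of -0.25. Among those that fell, Kcne1 differed by -0.98 ± 0.23 (edgeR adjusted p = 0.0523, and 0.0321 with the replicate number as a block), and 7 fell with that block. The ion channel list was called by camera (adjusted p = 3.0e-06) but not with an estimated correlation (adjusted p = 0.203). The calls of Slc3a2 and Shmt1 were lost without 11 and 13 single libraries of the 15, with edgeR adjusted p of up to 0.115 and 0.15.

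Of 23 fetal and stress-induced cardiac genes Uchl1 rose (2 when adjusted over the list alone or with the block), and Nppa stood at 872 ± 380 against 290 ± 150 CPM (1.59 ± 0.37, edgeR adjusted p = 0.0566, 0.0296 with the replicate number as a block, 0.0461 without DDIT3 replicate 3, 0.0401 without GFP replicate 2 and 0.00536 to 0.215 over 27 alternatives). Of 11 atrial markers Stard10 rose (0.96 ± 0.14), 2 rose and 1 fell when adjusted over the list alone or with the block. In the lists of adult sarcomere, coupling, fatty acid, mitochondrial regulator, tricarboxylic acid cycle, respiratory, ER, aminoacyl-tRNA synthetase, NRF2, autophagy, cell cycle, interferon and mitochondrial chaperone genes 0 members passed edgeR over all genes, among 1147 of 11814 tested genes with an unadjusted p below 0.05. Examples were Myh6 (-0.17 ± 0.14), Hspa5 (-0.27 ± 0.14), Ndufs1 (-0.05 ± 0.12) and Acadm (0.01 ± 0.09). Glycolysis and p53 lists had 0 calls over all genes and 1 each when adjusted over the list alone. With the block 1 synthetase, 1 interferon-stimulated and 1 glycolysis gene rose and 1 ER, 1 NRF2, 1 cell cycle and 1 glycolysis gene fell. The list of the tricarboxylic acid cycle and pyruvate dehydrogenase (camera adjusted p = 0.103) was called with the replicate number as a block (adjusted p = 0.0466) and without DDIT3 replicate 4 or 5 or GFP replicate 1 or 3 (adjusted p between 0.0241 and 0.0480). Over its alternatives the adjusted p ran from 0.0107 to 0.978 (the latter with an estimated correlation). Fbln1 fell among 13 fibroblast markers (-0.88 ± 0.14, 2 members with the block), with a list median of -0.50. Camera called fibroblast, endothelial and immediate early genes lower and ribosomal protein genes higher with the preset correlation, and none of these with an estimated correlation (adjusted p = 0.962, 0.962, 0.962 and 0.978) or by fry. The calls of the endothelial and immediate early lists were lost without DDIT3 replicate 5 or GFP replicate 2 (adjusted p of up to 0.119). That of the immediate early list was also lost without GFP replicate 1. That of the ribosomal list was lost without DDIT3 replicate 1 or 4 or GFP replicate 1, 3 or 5 (up to 0.350). Camera called the ER, interferon and pericyte lists, at adjusted p of 0.141, 0.142 and 0.141 with all libraries, without DDIT3 replicate 4 (0.0105, 0.00843 and 0.00843). It also called the ER list without GFP replicate 1 or 3, the interferon list without GFP replicate 3, 4 or 5 and the pericyte list without DDIT3 replicate 3 or GFP replicate 5. With block and sex together camera called the interferon and pericyte lists (adjusted p = 0.00669 and 0.00675) and lost the ribosomal list (0.13). Among male libraries alone it called the interferon list (8.15e-05), and without the libraries numbered 2 it lost the endothelial list (0.233). The mean log2 CPM of the fibroblast markers differed from GFP by -0.524 (two-sided exact permutation p = 0.0952, Benjamini-Hochberg adjusted 0.222, n = 5) and that of the endothelial markers by -0.283 (exact permutation p = 0.278, adjusted 0.417).

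In total 102 genes passed edgeR's quasi-likelihood test (62 higher, 40 lower in DDIT3), 52 of them at least 2-fold different, and 322 passed with the replicate number as a block (183 higher, 139 lower), including all 102. In 338 genes (2.86%) the libraries of the groups did not overlap, where chance gives 0.794%. Without DDIT3 replicate 1, 2 or 3 the count was 55, 62 or 65, and without GFP replicate 1, 3 or 4 it was 65, 63 or 61. The authors' deposited table for this comparison gave 241 genes at an adjusted p below 0.05 (126 higher, 115 lower), which included all but 1 of the 102, in the same direction.

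The third comparison set the ATF4 and DDIT3 groups against each other and tested whether their effects differed. ATF4 was higher than DDIT3 for Fgf21 (11.09 ± 0.36, edgeR adjusted p = 4.6e-14) and Phgdh (10.60 ± 0.28, adjusted p = 4.7e-15). Slc7a3 had 2 counts in DDIT3 and Cntnap3 had 1, ratios of 5808 (95% counting interval 1607 to 47964) and 2589 (464 to 102299). Slc7a11 and Mei4 had no count in DDIT3 and were at least 1359-fold and 209-fold higher in ATF4. DDIT3 was higher for Ddit3 (-4.84 ± 0.19), Acsl6, an acyl-CoA synthetase (-3.13 ± 0.23), Pdzd3 (-2.83 ± 0.27), Dbh (-2.62 ± 0.33), Pdzrn4 (-2.33 ± 0.30) and Fndc4 (-2.27 ± 0.23, edgeR adjusted p of 1.14e-05 or less). The list of amino acid response genes was higher in ATF4 in 34 of 39 members and that of DDIT3 (CHOP) targets in 12 of 20 (13 when adjusted over the list alone). Complex I was lower in 31 of 35 members and complexes II to V in 34 of 37 (32 and 34 when adjusted over the list alone), with an adjusted p = 0.372 for both with an estimated correlation. Endothelial markers were higher in 13 of 14 members, interferon-stimulated genes in 11 of 19 (15 when adjusted over the list alone) and pericyte and smooth muscle markers in 7 of 11 (8 when adjusted over the list alone), with adjusted p = 0.322, 0.486 and 0.405 with an estimated correlation. The call of the pericyte list by camera (adjusted p = 0.022) was lost without DDIT3 replicate 2 (adjusted p = 0.0555). In total 3997 genes passed edgeR (2106 higher, 1891 lower in ATF4), and camera called 19 of 29 lists, 7 of them with an estimated correlation.

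Uchl1 and Slc17a7 (0.96 ± 0.23 in ATF4) rose and Fbln1, Ces1d, Pknox2 and Wif1 fell in both groups against GFP, while Wisp1 (2.12 ± 0.21 in ATF4, -1.40 ± 0.25 in DDIT3) and Gstm2 (1.45 ± 0.16 and -1.29 ± 0.16) rose in ATF4 and fell in DDIT3. Pdzd3 (-1.51 ± 0.28 and 1.31 ± 0.24) and Clec2l went the other way, Clec2l with 3 counts in ATF4, 32 in GFP and 91 in DDIT3, a ratio of GFP to ATF4 of 11.1 (95% counting interval 3.46 to 56.4). The call of Clec2l in DDIT3 (edgeR adjusted p = 0.0474) was lost without 12 single libraries of the 15 (up to 0.139). Across the 11814 genes the log2 fold changes of the ATF4 and DDIT3 groups had a Pearson correlation of 0.132 (Spearman 0.1502). Genes are not independent replicates, and both comparisons use the same GFP libraries: 20 simulated pairs of unchanged groups against shared controls gave a correlation of 0.506 (0.464 to 0.531). The observed correlation also holds the large ATF4 changes in its spread, so that it cannot be set beside the simulated one. The covariance was 0.0403 against 0.0322 simulated (up to 0.0347), a difference of 0.00812. The simulated libraries were independent, while same-numbered ones deviated together. In a check added after these values were seen, on log2 CPM, the observed covariance was 0.0335. Without any change, the libraries' own deviations gave 0.0253 if independent and 0.0197 if same-numbered libraries share a level. With the GFP libraries split so that each comparison had its own, the correlation averaged 0.0583 (-0.0664 to 0.162 over 20 splits), where such a shared level moves the covariance by -0.00558. Of genes called in both comparisons 26 rose in both and 23 fell in both, where independent lists of these sizes would share 10.2 and 6.26, and 8 and 7 went opposite ways, where they would share 6.61 and 9.70. With split controls the 2 counts ran from 3 to 14 and from 0 to 11. These fits had fewer GFP libraries per comparison and called 1904 to 3566 genes in ATF4 and 8 to 68 in DDIT3. Their counts therefore cannot be set directly beside 26 and 23.

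**Figure D3:**
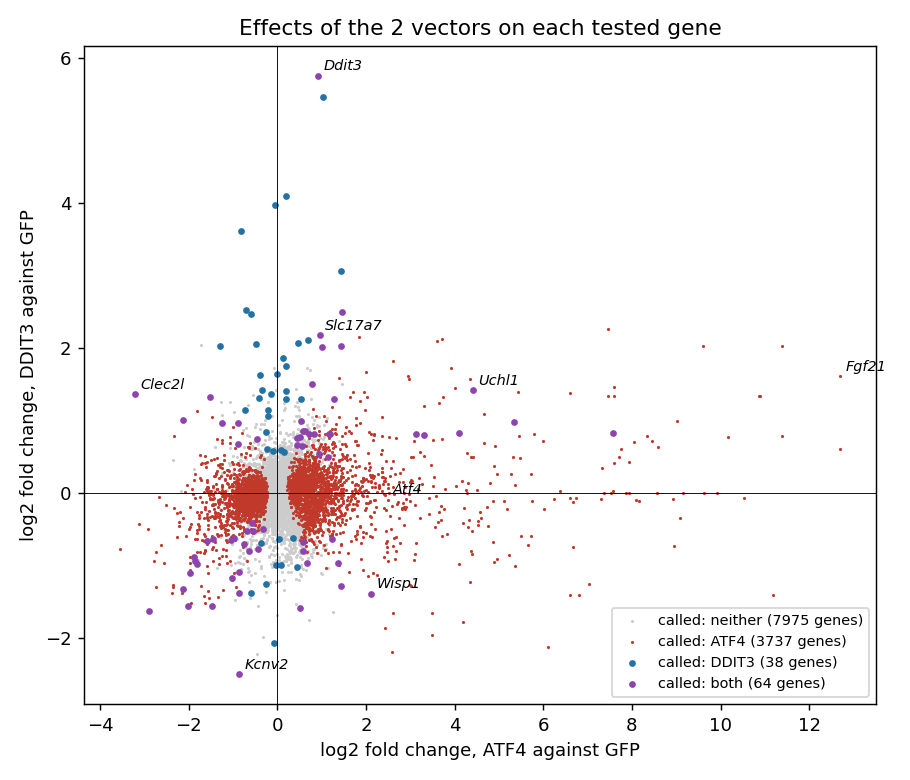
Log2 fold change of each of the 11814 tested genes in ATF4 (horizontal axis) and in DDIT3 (vertical axis) against GFP, coloured by the comparison in which edgeR called it. The 3737 genes called in ATF4 alone spread along the horizontal axis, and 38 genes were called in DDIT3 alone and 64 in both.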

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

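The tests of a lower cardiomyocyte share, sex, clock phase, scaling, a lower share of cardiomyocyte RNA and its displacement by endothelial RNA were chosen only after the results they weigh were seen.

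Of 379 groups of 5 values (the log2 CPM of the genes named by the rule, where a group averaged at least 10 counts, the marker scores and 3 measures of the libraries), 21 held a library whose gap to the nearest other took more of the group's range than Dixon's 95% critical value for 5, where chance gives about 18.9 (1 in 20). The gaps were measured on log2 CPM and the values below are CPM, so that on CPM itself other genes can stand out, as Myh7 does in ATF4 replicate 2. ATF4 replicate 2 was the lowest of its group 7 times: Acta1 415.9 CPM (others 1106 to 1617), Asns 1327 (1600 to 1697), Fam81a 4.251 (10.55 to 12.63), Hmox1 31.08 (46.54 to 49.09), Hspa9 1678 (2044 to 2216), Mthfd2 519.8 (720.9 to 808.4) and the leukocyte marker score 0.4471 (1.513 to 1.71). Atf4 itself was highest in this library, at 538 CPM (others of the ATF4 group 351 to 398). GFP replicate 4 was the lowest 5 times: Esrrg 56.88 CPM (77.02 to 86.29), Gnb3 4.609 (10.69 to 14.75), Ppargc1a 174.3 (241.7 to 274.2), Shmt1 7.11 (12.1 to 14.99) and Tnni1 0.395 (1.694 to 1.897). GFP replicate 5 was lowest for Eng at 41.56 CPM (84.36 to 93.22) and Ddit3 at 13.43 (15.77 to 16.63) and GFP replicate 1 for Mgst1 at 11.27 (21.6 to 22.13). DDIT3 replicate 4 was lowest for Acsl6 at 10.28 CPM (14.42 to 15.86) and highest for Pdzd3 at 21.6 (11.99 to 14.16), and DDIT3 replicate 3 was highest for Adap1 at 7.117 (5.793 to 6.116). DDIT3 replicate 5 was highest for Sdha at 3710 CPM (2993 to 3098) and Srxn1 at 37.32 (29.66 to 31.35) and lowest for Wif1 at 2.29 (3.774 to 4.343).

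Endothelial markers such as Tie1 and Eng were higher in ATF4, although the cells had been sorted. A lower share of cardiomyocytes, with all other cells raised alike, would raise fibroblast markers too. The endothelial minus fibroblast score rose by 0.783 in ATF4 against GFP (two-sided exact permutation p = 0.00794, n = 5), which argues against this as the whole cause. The score cannot test a lower share with only some other cell types raised. The pericyte score was 0.518 higher, but its test did not pass (exact permutation p = 0.0635, Benjamini-Hochberg adjusted 0.190), so that more cells of both types stay open. More endothelial cells or RNA passing the sorting gate could raise other endothelial genes too: in a second list of 28, the median log2 fold change was 0.702 (0.85 in the fixed list), 15 rose and 0 fell by edgeR, and Aqp1 stood at 331 against 173 CPM. A change of transcription within endothelial cells in response to ATF4-expressing cardiomyocytes stays open and was not tested.

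Same-numbered libraries of different groups deviated together. Sex is argued against as the whole cause: pairs of opposite sex had a mean correlation of 0.305 ± 0.159 (SD, n = 6) and pairs of the same sex one of 0.3003 ± 0.113 (n = 9). The time of day of the collection could be a source: the number took 88.9% of the within-group variance of an index of clock genes (median of permutations 30.8%, exact permutation p = 0.00632), with a mean deviation of the index from the group means of 1.36 in number 3 and -0.902 in number 4. The immediate early genes, which respond to dissociation, remain undecided, with 65.6% of the variance of their score (exact permutation p = 0.0577). The index was lower in ATF4 than in GFP by 0.620 on average (exact permutation p = 0.310, n = 5). It was lower in all 5 numbers, with differences from -1.26 to only -0.00393. The exact sign-flip p was 0.0625, the smallest that 5 pairs allow, so that a difference between these groups is not excluded.

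Respiratory complex genes such as Ndufs1 and Sdha were lower in ATF4. Scaling of the libraries is argued against: the median of the 72 members differed from that of the other tested genes by -0.609 (SD over the members 0.238). The members move together (estimated correlation 0.828 in complex I and 0.750 in complexes II to V), so that they are not replicates. Over libraries, the mean log2 CPM of the 72 differed by -0.570 (two-sided exact permutation p = 0.0159, n = 5). Gene length, GC content and expression level left a median residual of -0.376 (SD over the members 0.256), against a median of -0.582 before their removal. They are therefore argued against as the whole cause, but not as a part. A lower share of cardiomyocyte RNA, with other cells raised alike, is argued against as the whole cause by the endothelial minus fibroblast score given above (0.783). Displacement by endothelial RNA, alone or with pericyte RNA, cannot be told apart from a fall of these genes: the respiratory minus adult sarcomere score differed by -0.307 (exact permutation p = 0.119, n = 5), too wide a spread to decide. Displacement would lower the sarcomere, coupling and ion channel genes too (sarcomere score -0.263, exact permutation p = 0.00794). Acting alone, it would lower cardiomyocyte genes alike. The list medians were log2 fold changes of -0.307, -0.477 and -0.752, a difference that was not tested. Displacement stays open for the sarcomere, coupling and ion channel genes. Whether it could be the whole of the larger ion channel fall was not tested. A lowering of the respiratory and these other genes by ATF4 itself could also be the cause and was not tested apart from displacement.

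The group assignment was exchanged among the 10 libraries of each comparison, with 100 of the 126 possible splits run. For genes called by edgeR, 1 split of 100, the real one, reached the real count in ATF4 against GFP (3801, highest other 1), 1 in DDIT3 against GFP (102, highest other 3) and 1 in ATF4 against DDIT3 (3997, highest other 375). For gene lists called by camera, as many were reached in 19 of 100 splits for ATF4 against GFP (17, highest 24), in 77 for DDIT3 against GFP (5, highest 16) and in 18 for ATF4 against DDIT3 (19, highest 24). Of the 18 other splits that reached 17 lists, 14 kept 4 of the 5 ATF4 libraries together, as did 13 of the 17 in ATF4 against DDIT3, so that these carry part of the group difference. Of the 100 splits, 16 parted all 5 numbers, as a pairing by number would require. Among these 16 the real split alone reached its count of genes in each comparison (highest other 0), the smallest share that 16 splits allow. As many lists as in the real split were reached in 6 of the 16 for ATF4 against GFP. For DDIT3 against GFP it was 12, and for ATF4 against DDIT3 it was 7. Chance is not excluded for the counts of lists.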

How the results depend on the processing

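Fits with the replicate number and sex together, with male libraries alone and without the libraries numbered 2 were chosen only after the results were seen. No call of a named gene or list reversed. Over 27 alternatives (22 for lists), 94 of 100 called named genes kept their call in ATF4 against GFP, 18 of 26 in DDIT3 against GFP and 78 of 78 in ATF4 against DDIT3, and of lists 8 of 17, 0 of 5 and 7 of 19. Genes called ran from 3186 to 3854 without single libraries in ATF4 against GFP and from 3380 to 4093 in ATF4 against DDIT3. A 2-fold minimum left 1049 and 1310 by construction, and the block gave 5097 and 5228. In DDIT3 against GFP the 102 genes became 227 with DESeq2, 92 with limma-voom, 322 with the replicate block, 388 with block and sex, and, with fewer genes passing, 65 with the 5 CPM filter and 52 at 2-fold. Single libraries moved it from 55 to 146: 55, 62 and 65 without DDIT3 replicates 1, 2 and 3, and 65, 63 and 61 without GFP replicates 1, 3 and 4. Without ATF4 replicate 2 it was 146. Lists called with an estimated correlation were 8, 0 and 7, and by fry 1 in DDIT3 against GFP, where the 5 became 8 without DDIT3 replicate 4 and 3 without GFP replicate 2. Single libraries moved the lists from 17 to 20 in ATF4 against GFP and from 18 to 19 in ATF4 against DDIT3. The correlation of effects was 0.0908 to 0.190 without single libraries and 0.2898 without a filter (0.132 ± 0.102, jackknife SE). Among male libraries alone Rsad2, Pdgfrb, Ryr2 and Hspb1 in ATF4 (edgeR adjusted p = 0.148, 0.0825, 0.111 and 0.165) lost their calls, as did Wisp1 and Ankrd35 (0.0992 and 0.0592), Clec2l, Fam81a, Shmt1, Slc3a2 and Slit2 in DDIT3. With the replicate block Nppb was called in ATF4 against GFP (0.0251), and Hspa5 (0.00837) and Ppp1r15a (0.0478) in ATF4 against DDIT3; beyond the values given beside the results, it also called Mthfd2, Sema6c, Clcn1, Kcnj3 and Cenpf in DDIT3 against GFP (edgeR adjusted p = 0.0061 for Cenpf), and it changed no other call of a gene named in that comparison. Except where stated, the cause was not tested. In the simulated data for ATF4 against GFP, with 200 genes changed, edgeR recovered 28.4% of 1.5-fold changes and called 136 genes. The real comparison called 3801. The p-value cut-off after adjustment depends on how many genes change, so that this share cannot be carried over to the real ATF4 comparisons.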

Other observations

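The tests of neuronal genes and of induced neighbours were written before their results were seen, and the genes of the next paragraph were chosen after their values were seen.

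Several genes under 5 CPM rose further in DDIT3 than the genes the naming rule allows, apart from Ddit3 itself. Lhfpl4, a synaptic membrane protein, had 172 counts in DDIT3, 3 in GFP and 7 in ATF4, a ratio to GFP of 52.5 (95% counting interval 17.7 to 257). Mapk8ip2, a scaffold of the JNK pathway, had 104 counts against 5 (log2 fold change 4.09 ± 0.57), Padi2, a peptidylarginine deiminase, 96 against 5 (3.98 ± 0.62) and Tmem63c 127 against 9 (3.61 ± 0.61, edgeR adjusted p = 0.0051). Kcnj14 had 134 counts against 21 and Gng7 192 against 31.

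Since Slc17a7, Syt3 and Lhfpl4 are known from neurons, a list of 20 other neuronal and synaptic genes was tested in DDIT3 against GFP. Their median log2 fold change was 0.08, and camera gave p = 0.118 (0.154 with an estimated correlation). By edgeR 1 of 20 was called (Camk2b, 0.67 ± 0.14), where 0.863% of all tested genes were. A rise of neuronal genes as a class was thus not found. It is not excluded either, since the standard errors of the members ran from 0.129 to 0.559. Of the 105 genes at least 16-fold higher in ATF4 with a known position, 13 had another gene called at least 2-fold higher within 50 kb, among them Fgf21, Mthfd2 and P2rx3. Random genes gave 11.03 (permutation p = 0.301), and the share had a 95% interval of 6.76 to 20.2%, which argues against induced neighbours for most of them.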
